A study of Mus musculus with 12 samples.

How the data were processed

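Retinal RNA of C57BL/6J mice was sequenced in 12 libraries, 3 for each of 4 groups, per the labels. The groups were wild-type (WT) retina or retina with laser-induced choroidal neovascularisation (CNV), each after an intravitreal injection of vehicle (0.5X PBS) or cp-asiNRL. cp-asiNRL is a cell-penetrating asymmetric small interfering RNA against Nrl, given as 1 µl of 6 µg/µl per the labels. Libraries came from a kit for polyadenylated, strand-marked RNA, per the labels' protocols. The labels do not say how many animals gave each library or how long after injection tissue was taken, so p-values measure only the spread between these libraries.

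Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 and counted with featureCounts 1.6.0 on mm10. The chromosome accessions and coordinates in the deposited table are those of GRCm39, and only 769 of 38625 shared symbols had the same start in a GRCm38 table, so the coordinates printed here are GRCm39 as in the deposited file. The deposited signal is headed FPKM per the file headers, but each value multiplied by the gene length was a whole number within 1e-06 for all 482424 values (40202 genes, 12 libraries). The deposited signal is therefore reads divided by gene length, with no division by library total. The length equals the genomic span, introns included, for all 40200 genes with a single locus. Opposite-strand genes nested in a host with a mean above 1000 reads had a median 0.784 of the host's read density (2474 pairs), so reads of overlapping genes cannot be told apart here, and values of overlapping genes are uncertain.

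Reads per gene were recovered as signal times length and totalled 51298466 to 69394486 per library. Levels were expressed as CPM, the customary unit of reads scaled to the library total, with trimmed-mean scaling (trims of 30% and 5%). Genes were kept with a CPM equal to at least 10 reads at the median library size in at least 3 libraries and at least 15 reads in total, which left 25619 genes. log2(CPM + 1) was tested with limma 3.58.1 (trend) in R 4.3.3, with all 12 libraries in a model of 4 group means, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2(CPM + 1) scale, which understates changes of low genes. The design fixed before the data were examined named a count test for counts and limma on log2(value + 1) otherwise. Because the deposited values are a density and not counts as deposited, limma was used, and CPM took the place of the deposited density, which is not scaled to depth. DESeq2 was not used for the same reason, although limma voom on the recovered reads was an alternative. Since whole reads were recovered, the count test could have been run, and leaving it out departs from the design.

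The 30 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the 30 lists within a comparison. Camera with an estimated correlation and fry were the alternatives. Of 444 list entries 440 were in the table, and 13 mitochondrial symbols were matched to the names in the file. Single values of Nrl were also compared with an exact two-sided permutation test.

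Genes named in the text follow a rule fixed before the data were examined. It took Nrl in each comparison, fixed rod, cone and injury genes, the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, and up to 4 members with the smallest p of each list described. With no gene called, it took the 3 genes with the smallest p. The choice of described lists was made after the data were seen, by a rule: the rod and cone lists in both cp-asiNRL comparisons, and up to 6 further called lists with the smallest camera p. Unnamed gene models were left out of the largest changes. Not every gene the rule took is printed.

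The procedure was tested on simulated data with 200 changed genes per comparison. Simulated genes were drawn independently, with the same spread in all groups and no outlying library. Genes of the real libraries vary together, so the shares and false calls below need not hold for them. In the 12-library fit for cp-asiNRL in WT retina (25590 genes), 64% of genes changed 1.5-fold and 88% of genes changed 2-fold were recovered, with 5 false calls among 144. For the difference between the cp-asiNRL effects (25570 genes) these shares were 62% and 78%, with 1 false call among 123. Libraries of a group differed by 4.2 to 49.6 in chi-square per gene, so no library was a copy of another of its group. Libraries of different groups were not compared in this way. Alternatives covered the scaling, the filter, the pseudocount, the libraries in the fit, the replicate number as a block, sample quality weights, a fold threshold and leaving out each library. Removal of the trend with gene span, leaving out libraries outside a comparison and leaving out each library for the described lists and for rods under the laser were added after the data were seen. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.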

Results

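Retinal RNA was profiled in 12 libraries, in 4 groups of 3: WT retina with vehicle, WT retina with cp-asiNRL, laser CNV retina with vehicle and laser CNV retina with cp-asiNRL. Reads in genes ranged from 51298466 to 69394486 per library. The series asks about rod and cone-like expression after knockdown of Nrl, the transcription factor that directs photoreceptor precursors to the rod fate.

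Nrl (chromosome 14, 55756435 to 55762438, minus strand, GRCm39, no overlapping gene in the table) was measured in every library. In WT retina its level was 540.1 CPM ± 30.7 (SD, n = 3) with vehicle and 427.7 ± 36.0 (SD, n = 3) with cp-asiNRL, 20.8% lower, with each treated library below each vehicle library. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. In laser CNV retina Nrl was at 465.3 CPM ± 52.3 (SD, n = 3) with vehicle and 356.9 ± 113.6 (SD, n = 3) with cp-asiNRL (exact permutation p = 0.3). The library labelled CNV cp-asiNRL replicate 2 had 483.2 CPM, inside the range of the CNV vehicle libraries (422.7 to 523.7 CPM), whereas replicates 1 and 3 had 324.2 and 263.3 CPM. The log2 change of Nrl was -0.34 (SE 0.16, adjusted p = 0.318) in WT retina and -0.42 (SE 0.16, adjusted p = 0.25) in laser CNV retina in the limma fit of 12 libraries. With only the 6 WT libraries, Nrl fell by 0.35 on the log2 scale (adjusted p = 0.00093), and in the larger fit without the library labelled CNV cp-asiNRL replicate 2 its adjusted p in WT retina was 0.047. Without the library labelled CNV cp-asiNRL replicate 2, the change of Nrl in laser CNV retina was -0.66 (adjusted p = 0.000686). That library stands out here by its Nrl level, so leaving it out is no independent test of Nrl. Without CNV cp-asiNRL replicate 3 the change was -0.23. Across the limma fits with a library left out, the highest adjusted p of Nrl was 0.667 in WT and 0.658 in laser CNV retina.

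**Figure D1:**
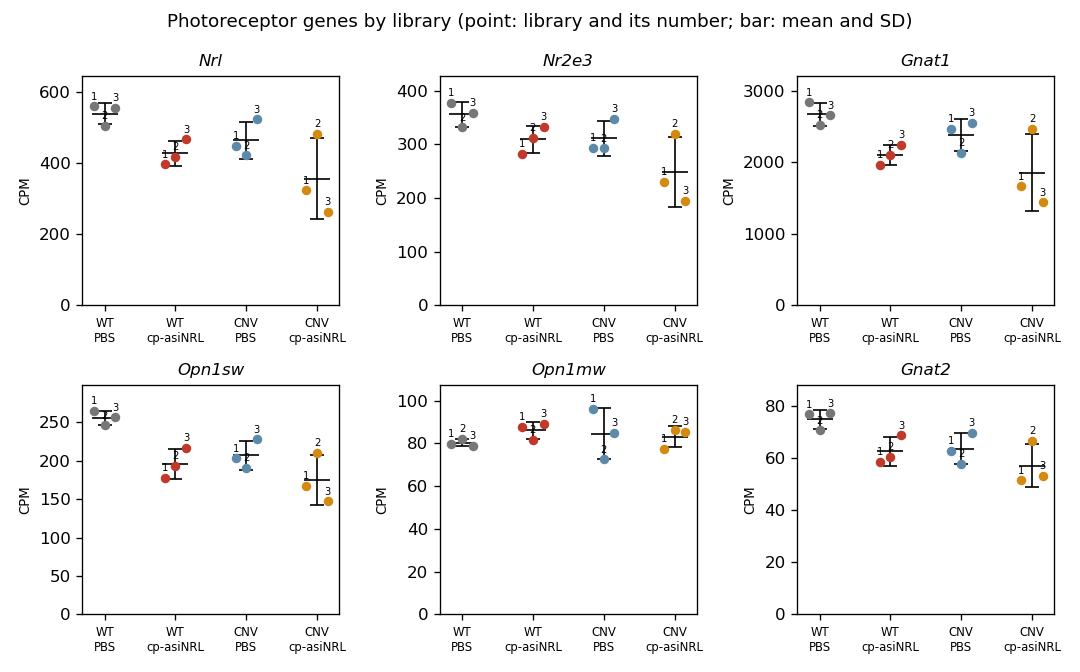
CPM (vertical axis, from 0) of Nrl, the rod genes Nr2e3 and Gnat1 and the cone genes Opn1sw, Opn1mw and Gnat2 in the 12 libraries by group (horizontal axis); points are libraries with their replicate number and bars are mean and SD. Nrl lies between 397.3 and 467.5 CPM in WT cp-asiNRL libraries and between 504.8 and 560.1 CPM in WT vehicle libraries.

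The first comparison asked which genes differed after cp-asiNRL in WT retina. Folh1, which encodes a glutamate carboxypeptidase, rose by a log2 change of 0.82 (SE 0.11, adjusted p = 0.0169), from 14.3 CPM ± 0.328 to 26.1 ± 3.55 (SD, n = 3 each). Etnppl (0.97), Slc12a1 (0.46) and Phex (0.46) rose as well, each in 3 of 3 treated libraries. Hspa5, which encodes the endoplasmic reticulum chaperone BiP, fell by 0.37 (SE 0.06, adjusted p = 0.0395) and Xbp1, a transcription factor of the unfolded protein response, fell by 0.36 (SE 0.06, adjusted p = 0.0395). The replication-dependent histone genes H4c14 and H4c4 fell by 0.48 and 0.44, and Trp53, Lipg and Mif fell by 0.46, 0.43 and 0.42. Such histone mRNAs lack a poly(A) tail, which the library kit selects for. Of 63 measured histone genes of this class, 52 were below 0 (mean -0.205, SE 0.026 over genes). Rn7sk, a small nuclear RNA without a tail, was at -0.44 (SE 0.20, adjusted p = 0.316). However, H4c14 and H4c4 span only 384 and 402 bp, and genes under 1 kb with a mean of at least 5 CPM had a median of -0.231. The histone mean was no lower than this median, but the histone genes were not held to the same 5 CPM floor. This comparison cannot separate short span from RNA capture, and a change in RNA capture was neither shown nor excluded for the histone calls. In all, limma called 36 of 25619 genes, 12 higher and 24 lower. With the trend with gene span removed, 4 genes were called higher (Folh1 among them, but not Etnppl, Slc12a1 or Phex), and none of the 24 lower calls passed (lowest adjusted p = 0.0561). Their median log2 change was then -0.34 (median SE 0.061), against -0.38 (median SE 0.064) before, and all 24 were still below 0. Hspa5 overlaps Rabepk on the other strand, and Rabepk was called too, so their reads are not separable.

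Rod genes were lower in all 15 measured members, with a mean log2 change of -0.17, and camera called the list (adjusted p = 0.0158; adjusted p = 0.688 with an estimated correlation). No member was called by limma, over all genes or adjusted over the list alone; 5 were called in the fit of the 6 WT libraries. Rom1 was at -0.41 (SE 0.14), Gnat1 at -0.35 (SE 0.15), Pde6g at -0.27 (SE 0.13) and Nr2e3, a rod factor downstream of Nrl, at -0.20 (SE 0.13). Cone genes were lower too, with a mean of -0.16 and 11 of 13 members below 0 (camera adjusted p = 0.00134; adjusted p = 0.688 with an estimated correlation). With only the 6 WT libraries limma called 6 cone genes lower. In the fit of all libraries no cone gene was called over all genes, and 4 were lower when adjusted over the list alone. These include Pde6h at -0.38 (SE 0.08), Gngt2 at -0.40 (SE 0.09) and Opn1sw, the short-wave cone opsin, at -0.39 (SE 0.11), while Opn1mw, the medium-wave opsin, was at 0.10 (SE 0.08, adjusted p = 0.585). On the other strand Opn1sw overlaps Calu, Rom1 overlaps Eml3, Pde6b overlaps Gm34254 and Thrb overlaps LOC115488350. Gnat2, at -0.26, was the fourth cone gene lower adjusted over the list alone. Further fixed photoreceptor genes did not pass over all genes in the fit of all libraries. Their values were -0.25 for Arr3, -0.04 for Thrb, -0.13 for Pde6b, -0.07 for Cnga1, -0.18 for Esrrb, -0.12 for Crx and -0.14 for Otx2. Of these, Arr3, Esrrb and Otx2 passed with only the 6 WT libraries. Without WT cp-asiNRL replicate 1 the rod list had a mean of -0.12 and was not called (adjusted p = 0.213).

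Cholesterol synthesis genes were lower in 15 of 16 members, among them Insig1 (-0.33, SE 0.12), with a list mean of -0.20 (camera adjusted p = 5.53e-06; adjusted p = 0.688 with an estimated correlation). The unfolded protein list had a mean of -0.17 (camera adjusted p = 0.00111; adjusted p = 0.688 with an estimated correlation), with Hspa5 and Xbp1 called over all genes and 3 members adjusted over the list alone. Pigment epithelium genes had a mean of -0.30, with Ttr at -0.87 (SE 0.16) and Rgr at -0.65 (SE 0.19), 0 members called by limma over all genes and 5 lower adjusted over the list alone (camera adjusted p = 0.00118; adjusted p = 0.688 with an estimated correlation). Ganglion cell genes had a mean of -0.12, with Nefh at -0.32 (SE 0.07) and 5 members lower adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.688 with an estimated correlation). Injury genes had a mean of 0.47 and microglial genes of 0.38, with Fgf2 at 0.87 (SE 0.30) and Cd44 at 0.64 (SE 0.29). In the fit of all libraries no member of either list was called over all genes or adjusted over the list alone. With only the WT libraries, limma called 8 of 19 injury and 2 of 20 microglial members higher. That smaller fit also called 10 cholesterol, 7 pigment epithelium, 4 unfolded protein and 4 ganglion members lower. Camera gave adjusted p = 0.00118 and 0.00543 for the injury and microglial lists, and adjusted p = 0.688 with an estimated correlation for both. Without WT cp-asiNRL replicate 1 their means were 0.22 and 0.09 and neither list was called (adjusted p = 0.272 and 0.555), and without WT vehicle replicate 2 the ganglion list was not called (mean -0.10, adjusted p = 0.0752). On the other strand Insig1 overlaps Gm35223, Rgr overlaps Lrit1, Nefh overlaps Ap1b1 and Fgf2 overlaps Nudt6. WT cp-asiNRL replicate 1 had 12.7 CPM of Serpina3n, an acute-phase gene of reactive glia, against 2.04 and 1.41 CPM in replicates 2 and 3.

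The number of called genes rested on the fit. With only the 6 WT libraries limma called 2245 genes (621 higher, 1624 lower), and leaving out any library of these groups from the 12-library fit left 1 to 8. The balance then turned to higher genes, with 7 higher and 1 lower without WT vehicle replicate 3, 3 and 1 without WT cp-asiNRL replicate 2, and only higher genes without the others. Of the other libraries, leaving out CNV vehicle replicate 2 left 6 genes (5 higher, 1 lower) and leaving out the library labelled CNV cp-asiNRL replicate 2 gave 773 (176 higher, 597 lower).

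The second comparison asked which genes differed after cp-asiNRL in laser CNV retina. St8sia2, a polysialyltransferase, rose by a log2 change of 0.50 (SE 0.06, adjusted p = 0.0179) and Dbp, a circadian transcription factor, rose by 0.45 (SE 0.07, adjusted p = 0.0394; it overlaps Sphk2 on the other strand). Samd7, a photoreceptor regulator that keeps cone and other genes silent in rods, fell by 0.47 (SE 0.07, adjusted p = 0.0337), although the unnamed gene model Gm33590, also lower, overlaps it on the other strand. Smug1, a DNA repair glycosylase, fell by 0.52, the histone gene H4c14 by 0.55, Hmgn2 by 0.47 and the disulfide isomerase Pdia6 by 0.36. In all, limma called 12 genes, 4 higher and 8 lower, but 3 higher and 0 lower with no filter on low values. For H4c14 a change in RNA capture was neither shown nor excluded here either. Of the 63 histone genes 44 were below 0 (mean -0.124, SE 0.025 over genes). Genes under 1 kb with a mean of at least 5 CPM, a floor not set for the histone genes, had a median of -0.172. Rn7sk was at -0.35 (SE 0.20). Smug1, H4c14, Pdia6, Rabepk and Gm30188 were the 5 genes called in both cp-asiNRL comparisons.

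Rod genes were lower in all 15 members, with a mean log2 change of -0.34 (camera adjusted p = 6.62e-08; adjusted p = 0.544 with an estimated correlation). No rod gene was called over all genes and 10 were lower adjusted over the list alone, among them Gngt1 at -0.47 (SE 0.14) and Cnga1 at -0.31 (SE 0.11). Genes shared by rods and cones had a mean of -0.27 (camera adjusted p = 9.41e-11; adjusted p = 0.544 with an estimated correlation), with none called over all genes and 5 lower adjusted over the list alone, such as Rcvrn at -0.34 (SE 0.11). The photoreceptor fate list had a mean of -0.21 (camera adjusted p = 1.62e-06; adjusted p = 0.544 with an estimated correlation), with Samd7 called over all genes and 8 members lower adjusted over the list alone, Otx2 (-0.23, SE 0.07) and Pias3 (-0.38, SE 0.07) included. The cone list was not called (mean -0.06, camera adjusted p = 0.164), and Opn1sw was at -0.26 (SE 0.11), Opn1mw at -0.02 (SE 0.08) and Arr3 at -0.06 (SE 0.12). Nr2e3 at -0.35, Gnat1 at -0.39, Crx at -0.28 and Thrb at -0.22 were lower adjusted over the rod or the fate list alone and did not pass over all genes. Gnat2 at -0.16, Pde6h at 0.001, Pde6b at -0.28 and Esrrb at -0.33 passed neither way. Rcvrn overlaps Glp2r and Pias3 overlaps Nudt17 on the other strand. Without the library labelled CNV cp-asiNRL replicate 2 the means of the rod and shared lists were -0.54 and -0.415, and without replicate 3 they were -0.19 and -0.17. Pde6h, Arr3 and Opn1mw changed sign under some alternatives. Without CNV vehicle replicate 2 the cone list had a mean of -0.10 and was called (adjusted p = 0.0105).

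Interferon response genes were higher in all 23 members, with a mean of 0.76 (camera adjusted p = 3.81e-13; adjusted p = 0.544 with an estimated correlation). None was called over all genes and 21 were higher adjusted over the list alone, among them Oasl2 (1.16, SE 0.35) and Gbp3 (1.04, SE 0.30). Microglial and injury genes had means of 0.48 and 0.50, with no member called over all genes or adjusted over the list alone (camera adjusted p = 3.72e-05 and 0.000193; adjusted p = 0.615 and adjusted p = 0.625 with an estimated correlation). Cholesterol synthesis genes had a mean of -0.16, with Idi1 at -0.31 (SE 0.09) and 2 members lower adjusted over the list alone (camera adjusted p = 6.61e-05; adjusted p = 0.615 with an estimated correlation). The library labelled CNV cp-asiNRL replicate 2 stood apart from replicates 1 and 3 beside these lists: Gfap was at 10.7 CPM against 41.6 and 40.7, and Oasl2 at 5.93 against 14.1 and 26.3. Without it the means of the interferon, microglial, injury and cholesterol lists were 1.17, 0.85, 0.90 and -0.25, and without replicate 3 they were 0.39, 0.28, 0.25 and -0.10. The microglial and injury means were 0.77 and 0.85 without CNV vehicle replicate 2 and 0.29 and 0.28 without CNV vehicle replicate 1, where the injury list was not called (adjusted p = 0.0654). The microglial mean was 0.32 without CNV cp-asiNRL replicate 1. Without the library labelled CNV cp-asiNRL replicate 2 limma called 4481 genes, 2268 higher and 2213 lower. Leaving out any other library of these groups left 0 to 6, with 4 higher and 2 lower without CNV cp-asiNRL replicate 1, 3 and 2 without replicate 3, 1 and 1 without CNV vehicle replicate 2 or 3, and none without CNV vehicle replicate 1. Leaving out WT cp-asiNRL replicate 1 left 4 (2 higher, 2 lower), and with only the 6 laser libraries it called 0 (2416 at unadjusted p under 0.05; 2917 with limma voom and sample quality weights in the 12-library fit).

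**Figure D2:**
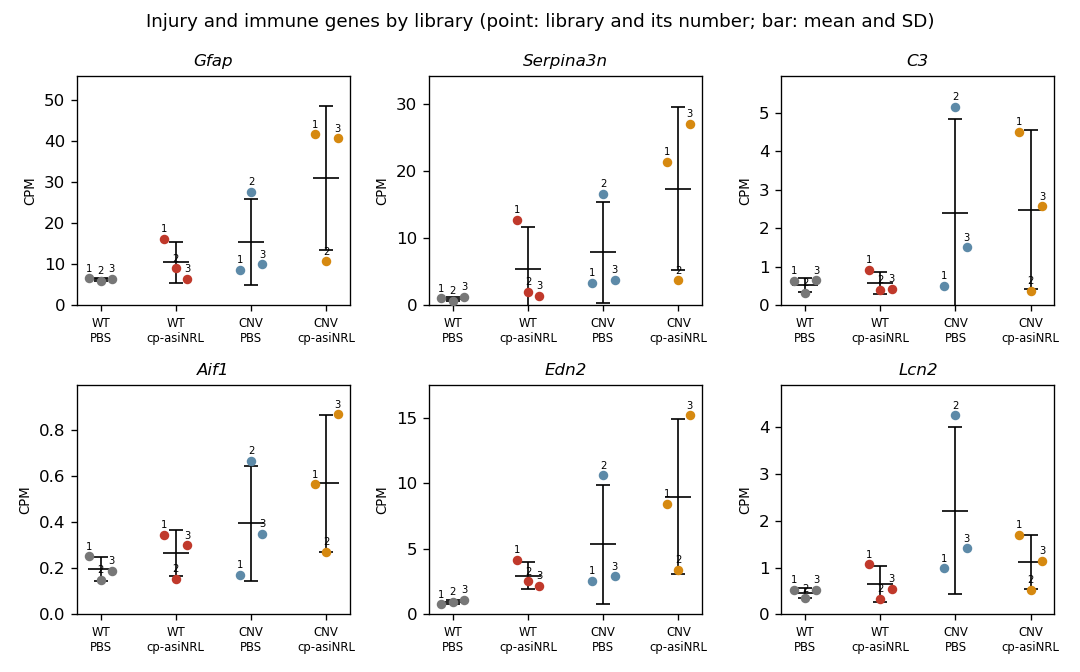
CPM (vertical axis, from 0) of Gfap, Serpina3n, C3, Aif1, Edn2 and Lcn2 in the 12 libraries by group (horizontal axis); points are libraries with their replicate number and bars are mean and SD. Gfap is at 27.6 CPM in CNV vehicle replicate 2 and at 8.65 and 10.02 CPM in replicates 1 and 3.

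The third comparison asked what the laser model changed under vehicle. No gene was called by limma in the 12-library fit (0 of 25619; 1965 at unadjusted p under 0.05; 34 with limma voom and sample quality weights; 169 with only the 6 vehicle libraries, 136 higher and 33 lower). Leaving out the library labelled CNV cp-asiNRL replicate 2 gave 74 genes, and leaving out CNV vehicle replicate 3 gave 1. The smallest p belonged to Optc, a vitreous proteoglycan gene (0.98, SE 0.14), Folh1 (0.71, SE 0.11) and the gene model Gm36284 (0.58, SE 0.09), each at adjusted p = 0.0577 and higher in 3 of 3 laser libraries; Gm36284 overlaps Ppm1h on the other strand. Among injury genes Serpina3n was at 1.86 (SE 0.69), Edn2 at 1.501 (SE 0.43, overlapping Gm36134 on the other strand), Lcn2 at 1.004 (SE 0.28), Gfap, the glial filament gene, at 0.98 (SE 0.46) and C3 at 0.90 (SE 0.45). None of these passed over all genes in the 12-library fit. With only the 6 vehicle libraries limma called Serpina3n (adjusted p = 0.0201) and Edn2 (adjusted p = 0.0253), but not Lcn2, Gfap or C3. Aif1 (0.21, SE 0.13), Ccl2 (0.15, SE 0.21), Vegfa (-0.14, SE 0.07), Rpe65 (0.11, SE 0.15) and Cdh5 (0.21, SE 0.13) did not pass in the 12-library fit either, nor did Opn1sw (-0.31, SE 0.11) or Nrl (-0.22, SE 0.16). The ratio of mean CPM was 18.5 for Ccl2, 2.0 for Aif1, 4.5 for C3 and 4.8 for Lcn2, so the log2 values understate the changes of these low genes. For Ccl2, Aif1 and C3 the libraries of the groups overlapped. The rod list was lower under the laser alone in 14 of 15 members, with a mean of -0.142 (camera adjusted p = 0.00829; adjusted p = 0.647 with an estimated correlation), against -0.173 after cp-asiNRL in WT retina. Without CNV vehicle replicate 2 its mean was -0.07 and it was not called (adjusted p = 0.301). Both rod means are taken against the same WT vehicle libraries, so they are not independent. The cone (-0.06), shared (-0.07) and fate (-0.01) lists were not called.

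Injury genes had a mean log2 change of 0.82, with 8 of 19 members higher adjusted over the list alone (camera adjusted p = 1.38e-12; adjusted p = 0.488 with an estimated correlation). Complement genes had a mean of 0.58 and a median of 0.34, with C4b at 1.58 (SE 0.49) and 4 members higher adjusted over the list alone (camera adjusted p = 1.24e-06; adjusted p = 0.488 with an estimated correlation). Matrix genes had a mean of 0.24, with Ccn2 at 0.69 (SE 0.14) and 2 members higher adjusted over the list alone (camera adjusted p = 6.23e-07; adjusted p = 0.488 with an estimated correlation). Microglial and interferon genes had means of 0.67 and 0.43, with C1qb at 1.15 (SE 0.41) and Oasl2 at 0.84 (SE 0.35), and no member adjusted over the list alone (camera adjusted p = 1.95e-10 and 1.19e-06; adjusted p = 0.488 with an estimated correlation for both). Cholesterol synthesis genes were lower in 15 of 16 members, with a mean of -0.29 and 14 lower adjusted over the list alone, Fdps (-0.55, SE 0.12) among them (camera adjusted p = 5.27e-16; adjusted p = 0.488 with an estimated correlation). No member of these 6 lists was called over all genes in the fit of all libraries. With only the 6 vehicle libraries, limma called 6 injury, 5 microglial, 10 interferon, 3 complement and 1 matrix members higher. In that smaller fit 6 cholesterol members were called lower. Without CNV vehicle replicate 2 the injury, complement, microglial and matrix means were 0.47, 0.35, 0.38 and 0.098, and camera still called each of these lists (highest adjusted p = 0.03). Ccn2 overlaps Gm15270 on the other strand.

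The fourth comparison asked whether the effect of cp-asiNRL differed between laser CNV and WT retina. No gene was called by limma (0 of 25619; 1591 at unadjusted p under 0.05; 0 with limma voom and sample quality weights), and Nrl differed by -0.09 (SE 0.22, adjusted p = 0.952). Etnppl had the smallest p, with a difference of -1.18 (SE 0.23, adjusted p = 0.788). Without the library labelled CNV cp-asiNRL replicate 2, 12 genes were called, 2 higher and 10 lower.

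Interferon genes had a higher log2 change after cp-asiNRL in laser CNV than in WT retina in all 23 members, Isg15 at 0.61 (SE 0.24) among them. The mean difference was 0.54 (camera adjusted p = 2.61e-06, and 0.83 with an estimated correlation). In WT retina this list was higher too, with a mean of 0.23 and 20 members above 0 (camera adjusted p = 0.0406, and 0.688 with an estimated correlation). Its score was 0.603 in WT cp-asiNRL replicate 1, against 0.089 and -0.014 in replicates 2 and 3. Ganglion cell genes had a mean difference of 0.15 (camera adjusted p = 0.00721; adjusted p = 0.83 with an estimated correlation) and 3 members higher adjusted over the list alone. The mean difference was -0.16 for genes shared by rods and cones (camera adjusted p = 8.58e-05), -0.16 for rod genes (camera adjusted p = 0.0171), and -0.10 and -0.11 for photoreceptor fate and mitochondrially encoded genes (camera adjusted p = 0.0242 for both). With an estimated correlation, adjusted p = 0.882 for rod genes and 0.83 for the other 3 of these lists. No member of the 6 lists was called over all genes, and outside the ganglion list none was called adjusted over the list alone. Isg15 overlaps Gm46878 on the other strand.

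Apart from the ganglion list, these differences rested on single libraries. Without CNV cp-asiNRL replicate 3 the interferon difference was 0.16 (adjusted p = 0.0502), the shared -0.06 (adjusted p = 0.0628), the fate -0.05 (adjusted p = 0.263) and the rod -0.02 (adjusted p = 0.806), none of them called. Without the library labelled CNV cp-asiNRL replicate 2 they were 0.94, -0.30, -0.165 and -0.37. The rod list was not called either without WT vehicle replicate 2, WT cp-asiNRL replicate 3, CNV vehicle replicates 1 or 3 or CNV cp-asiNRL replicate 1 (-0.108), with a highest adjusted p of 0.13. The fate list was not called without WT vehicle replicates 1 or 3, WT cp-asiNRL replicate 3, CNV vehicle replicate 3 or CNV cp-asiNRL replicate 1, with a highest adjusted p of 0.134. The mitochondrial list was at -0.02 without CNV vehicle replicate 1 (adjusted p = 0.652), -0.065 without CNV cp-asiNRL replicate 1 (adjusted p = 0.167) and -0.18 without CNV vehicle replicate 2. It was not called without WT vehicle replicates 1 or 2 or WT cp-asiNRL replicates 1 or 3 either (highest adjusted p = 0.169). The ganglion list was called whichever library was left out, with a mean between 0.111 and 0.199.

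Across the 16642 genes with a mean of at least 2 CPM, the log2 changes in WT and laser CNV retina, which share no library, correlated with a Pearson coefficient of 0.511 and a Spearman coefficient of 0.464 across genes, which are not independent replicates.

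Each comparison of a pair of groups carried a trend with gene span. Among 13539 genes with a mean of at least 5 CPM, the median log2 change after cp-asiNRL in WT retina was -0.23 for genes under 1 kb and 0.07 for genes in the longest of 6 span classes, and the Spearman coefficient with span across genes was 0.528, against 0.352 in laser CNV retina and 0.388 for the laser under vehicle. The cone gene Opn1sw, for example, has a short span of 3843 bp. With the trend removed the rod and cone lists in WT retina had means of -0.17 and -0.16, and limma called 4 genes, all higher. The removed trend was fitted over all 25619 genes, low ones included, so for short expressed genes the removal was partial.

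**Figure D3:**
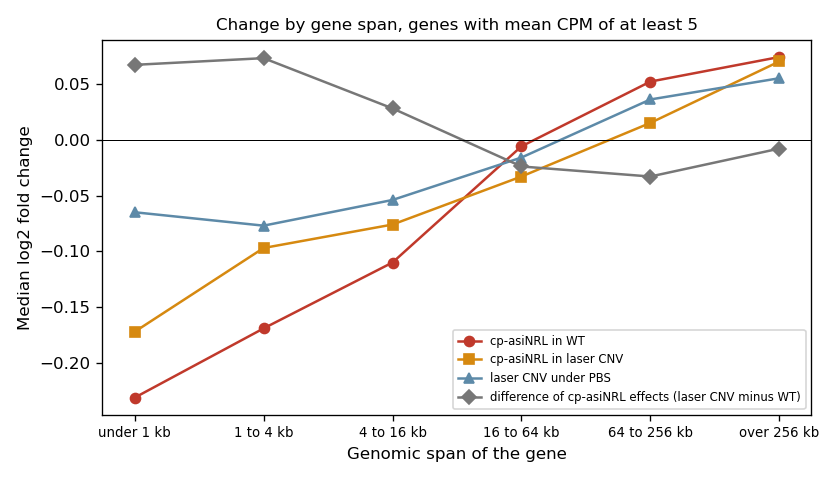
Median log2 fold change (vertical axis) of genes in 6 classes of genomic span (horizontal axis) for the 4 comparisons, over 13539 genes with a mean of at least 5 CPM. The medians after cp-asiNRL in WT retina go from -0.23 for genes under 1 kb to 0.07 for the longest class.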

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

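The tests of the splits and of receptor gene density were set before their results were seen, and the other tests in this part were chosen after. The effect of cp-asiNRL differed between laser CNV and WT retina for 6 lists in camera at the preset correlation. The mean difference of log2 changes (laser CNV minus WT) was 0.54 for interferon genes, 0.15 for ganglion cell genes, -0.16 for rod genes, -0.16 for genes shared by rods and cones, -0.10 for photoreceptor fate genes and -0.11 for mitochondrially encoded genes. None was called with an estimated correlation (lowest adjusted p = 0.83). Of 100 splits that reassigned treatment within each state, 70 gave at least 6 called lists, with 20 in the highest other split, so chance cannot be excluded. For single genes the real count was 0, which all 100 splits reach by construction, so they say nothing about chance. The highest other split gave 2638 genes. A split can bring the treatment effect itself into the difference, so such counts do not show a structure beyond treatment.

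For the comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. In WT retina the real split called 36 genes and the highest other split 0, and 1 of 10 splits reached the real count. In laser CNV retina the real split called 12 genes and 2 of 10 splits reached that. The highest other, with 2943 genes, exchanges the libraries labelled replicate 2 of both groups. It keeps replicates 1 and 3 of each group on their own side, so the treatment effect can enter this count, and the count alone does not show its cause. For the laser under vehicle all 10 splits reached the real count of 0, the highest other being 0 as well. Called lists numbered 11, 11 and 14 in these comparisons, and 3, 6 and 3 of the 10 splits reached that, with 11, 20 and 15 in the highest other.

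The library labelled CNV cp-asiNRL replicate 2 had a score of 0.145 over the 2245 genes called between the 6 WT libraries, against 0.347 and 0.346 in replicates 1 and 3, and its depth of 67.3 M reads (58.4 and 65.3 M in the others) argues against lower depth. The highest CNV vehicle score was 0.182, which argues against a swap with a library that responded as replicates 1 and 3 did. It cannot exclude a swap with a weakly responding library. CNV vehicle replicate 2 (score 0.156) lay nearer to CNV cp-asiNRL replicates 1 and 3 in injury score (1.52 against 1.63 and 1.81), microglia score (1.247 against 1.479 and 1.557) and PC1 (9.85 against 17.1 and 23.76, the other CNV vehicle libraries being below 0). Its Nrl was also lower than in the library labelled CNV cp-asiNRL replicate 2 (log2 difference from WT vehicle -0.351 against -0.159). However, this Nrl value was nearer to CNV vehicle replicates 1 and 3 (-0.263 and -0.043) than to CNV cp-asiNRL replicates 1 and 3 (-0.733 and -1.032). The same held for its interferon score (0.566, against 0.373 and 0.357 with vehicle and 1.255 and 1.944 with cp-asiNRL). It also held for its share of Rn7sk (0.461%, against 0.403% and 0.379% with vehicle and 0.288% and 0.257% with cp-asiNRL). Exchanging these replicate 2 labels gave 2943 called genes, against 12 with the labels as given. Both libraries lay apart from the rest of their groups, so exchanging them can raise this count whatever set them apart. The count therefore says nothing about a swap. The levels above point both ways, and a swap of these libraries stays open. The score of 0.145 lies within the CNV vehicle range (0.073 to 0.182), and of these genes 21.3% lay past all CNV vehicle libraries on the treated side (25% by chance), against 69.4% and 63.7% in replicates 1 and 3, as a library without an effective dose or with a wrong label of its own may show. Against this, 25 of the 36 genes called in WT retina (Hspa5 and Xbp1 among them) lay past all CNV vehicle libraries on the treated side and 1 on the other, but the spread of that fit includes this library and favours such genes; of the 36 genes with the smallest p between the 6 WT libraries, 15 lay on the treated side and 0 on the other (24 and 30 on the treated side in replicates 1 and 3). A weaker response and a lesion that varies between animals stay open as untested.

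Rod and cone lists were both lower after cp-asiNRL in WT retina, and the trend with gene span does not account for this, since the lower of the list means was -0.167 after its removal and -0.173 before. The SEs over the genes of the list were 0.021 and 0.027. SEs of list means in this paragraph treat genes as independent and do not measure the spread between libraries. Rod genes had an estimated correlation of 0.874. A lower share of photoreceptors would raise all other cell types, but ganglion cell genes had a mean of -0.119 (SE 0.042). The other lists lay within 2 SE of 0, at 0.04 (SE 0.06) for horizontal, -0.05 (SE 0.04) for bipolar and amacrine and -0.02 (SE 0.06) for Muller glia, so this argument rests on the ganglion list. That list was at -0.08 (SE 0.04) with the span trend removed and was not called without WT vehicle replicate 2. Its SE also leaves out the spread between libraries, so the argument is narrow and a lower share of photoreceptors is not excluded. Knockdown of Nrl may lower rod genes, but the design offers no test of it apart from the treatment itself, and the call of both lists is lost with an estimated correlation. The laser alone gave a rod mean of -0.142 (-0.07 without CNV vehicle replicate 2). That comparison uses the same WT vehicle libraries, so these rod means are not independent.

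Genes of longer span were higher after cp-asiNRL in WT retina. Depth overlapped between the groups (54.5 M reads in the lowest treated library, 51.3 to 60.1 M with vehicle), which argues against depth. Olfactory and vomeronasal receptor genes, silent in most tissues, had 1.062 times the read density in treated libraries, with each treated library above each vehicle library, as genomic DNA may give. The added density would raise the 714 genes of the longest span class by a median of only 0.006 on the log2 scale, against 0.074 observed (SE 0.003 over genes, not libraries). This argues against genomic DNA as the whole of the trend. A change in the share of unspliced RNA or in the capture of RNA without a poly(A) tail stays open as untested.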

How the results depend on the processing

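Removal of the span trend, leaving out libraries outside a comparison, and leaving out libraries for lists other than rods and cones after cp-asiNRL were chosen after seeing the data. The counts of called genes depended on the processing, and the cause was not tested except where fewer libraries or genes entered the fit. Genes called by cp-asiNRL in WT retina (36) numbered 19 with RLE size factors (11 higher and 8 lower, against 12 and 24), 0 with no filter on low values, 17 with a pseudocount of 10, 1707 with limma voom and sample quality weights, 2245 with only the libraries of the compared groups, 1 at 2-fold or more, and 4 with the span trend removed (4 higher, 0 lower, against 24 lower). In laser CNV retina (12) they numbered 3 with no filter (3 higher, 0 lower, against 4 and 8), 2917 with voom and quality weights, 0 with only the compared groups and 0 at 2-fold or more. For the laser under vehicle (0) they numbered 34 with voom and quality weights and 169 with only the compared groups. Leaving out a library gave 1 to 773 genes in WT retina, 0 to 4481 in laser CNV retina, 0 to 74 for the laser under vehicle and 0 to 12 for the difference, the highest each time without the library labelled CNV cp-asiNRL replicate 2.

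With the replicate number as a block, 1 gene was called in WT retina, 4 in laser CNV retina and 0 in the other comparisons. Same-numbered libraries correlated between -0.517 and 0.401 in their deviations from the group means, so the numbers do not pair the libraries across all groups. Between WT vehicle and WT cp-asiNRL the same-numbered libraries correlated between 0.05 and 0.206, and the others between -0.257 and 0.115. Pairing within WT retina is therefore not excluded.

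Nrl kept its direction in WT and in laser CNV retina under the alternatives run. In WT retina it was called with only the compared groups (-0.35) and lay between -0.40 and -0.29 with a library left out; in laser CNV retina it was called with voom and quality weights (-0.59) and lay between -0.66 and -0.23. The list calls ended with an estimated correlation and with fry: for rods in WT retina (-0.17, adjusted p = 0.688 and 0.708), for cones in WT retina (-0.16, adjusted p = 0.688 and 0.273) and for rods in laser CNV retina (-0.34, adjusted p = 0.544 and 0.303). With a library left out the means lay between -0.21 and -0.12 for rods and -0.20 and -0.14 for cones in WT retina, and between -0.54 and -0.19 for rods and -0.098 and -0.026 for cones in laser CNV retina.

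Of 2749 values of named genes under an alternative, 14 changed sign, none of them called in either fit. In laser CNV retina Pde6h (0.001) was at -0.002 with RLE size factors, -0.07 with voom, -0.011 with the compared groups only, and between -0.042 and 0.066 with a library left out (negative values -0.018, -0.029, -0.023 and -0.042). Arr3 (-0.06) was at 0.007 and 0.058 without CNV vehicle replicates 1 and 3 (lowest -0.247), and Opn1mw (-0.019) at 0.077 and 0.03 without CNV vehicle replicate 1 and CNV cp-asiNRL replicate 1. Rpe65 (0.108) was at -0.022 without CNV vehicle replicate 1 for the laser (highest 0.271). The difference of the Nrl effects (-0.085) was at 0.003 without CNV vehicle replicate 3 and 0.109 without CNV cp-asiNRL replicate 3 (lowest -0.326). The count test of the design (edgeR) was not run although whole reads were recovered, which departs from the design. On the recovered reads limma voom was run.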

Other observations

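The genes in this paragraph were chosen after their values were seen. Beyond the genes named in the report, those called lower after cp-asiNRL in WT retina included Tpi1, a glycolytic enzyme (-0.40, SE 0.06, adjusted p = 0.0395), and the chaperones Calr (-0.39, SE 0.07) and Hspa8 (-0.30, SE 0.05). None of the 3 passed with the span trend removed (adjusted p = 0.0561, 0.0561 and 0.059). The gene model Gm765 had the largest rise, 1.06 (SE 0.11, adjusted p = 0.00238). Of the 36 genes called, 35 had the same sign in laser CNV retina. Rn7sk, which like the histone mRNAs of the report has no poly(A) tail, took 0.418% to 0.46% of reads in WT vehicle libraries and 0.314% to 0.345% in WT cp-asiNRL libraries. In laser CNV retina it took 0.379% to 0.461% with vehicle, 0.288% and 0.257% in cp-asiNRL replicates 1 and 3, and 0.516% in the library labelled replicate 2. In that library H4c14 was at 4.713 CPM, below the CNV vehicle libraries (lowest 6.302 CPM), so H4c14 and Rn7sk moved apart there.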
